A study of Bifidobacterium breve UCC2003 with 8 samples.

How the data were processed

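RNA of 4 regulator mutants of the gut bacterium *Bifidobacterium breve* UCC2003, named lntR, nahR, nagR1 and nagR2 in the labels, was compared with wild-type RNA on 8 two-colour Agilent arrays, 2 per mutant. Per the labels' protocols, mutant and wild-type cultures were grown apart, anaerobically, in a modified MRS medium with 1% (w/v) ribose as carbon source and 0.05% (w/v) cysteine, to an OD600 of 0.5. Per the labels, the mutant carried Cy3 and the wild type Cy5 on replicate 1 of each mutant, and the dyes were exchanged on replicate 2. The labels call the pair biological replicates and also call the second array a dye swap. They do not say whether a wild-type RNA was used for more than 1 mutant. All p-values therefore measure the spread between these arrays. If a pair is a technical dye swap of the same RNA, each mutant has 1 biological replicate and no p-value tests a difference between cultures.

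The deposited scanner files hold mean spot and median local background signals of both channels as intensity, per the file headers. Feature Extraction 9.5 made them, per the submitters' processing notes. The processed signals in the same files are intensity values that the authors' scanner software had background-corrected and dye-normalized, per the file headers. The headers record background method code 6 on the lntR and nahR arrays and code 1 on the nagR1 and nagR2 arrays, and these codes were not decoded. The deposited value table holds the log10 ratio of Cy5 over Cy3, per comparison with the scanner files. With a tolerance of 1% (and a small allowance for rounding near 0), 0 features differed from the scanner's log10 ratio on any array. Its array medians were 0 on the first 6 arrays, 0.0015 on nagR2 replicate 1 and -0.002 on nagR2 replicate 2. It had not been turned for the dye swap. The series' design text names the Cyber-T test with a p threshold of 0.001 and a ratio over 3 or under 0.33.

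The lntR arrays use a design with 10263 gene spots of 5664 probes, and the other 6 arrays a design with 43803 gene spots of 8262 probes. On the second design a gene can be split into numbered parts, which were joined. The mean number of spots per locus tag was 5.4 on the first design and 23.4 on the second. The depth of arrays is their brightness: the median mutant signal ran from 468.3 to 2222.6 and the median wild-type signal from 785.5 to 2206 intensity units. Between 93.6% and 99.1% of gene spots were well above background, per the flags in the files. Outlier-flagged spots were left out, at most 290 per array. Only nahR replicate 2 had saturated spots, 88 of them, which were kept. The number of arrays limits the precision.

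From the deposited intensities, background was corrected with normexp (offset 50) and each array was normalized by loess, in limma 3.58.1 under R 4.3.3, with control and outlier-flagged spots at weight 0. The log2 ratio was turned to mutant over wild type by the labels. Spots were averaged per probe and probes per locus tag, which left 1841 genes measured on all 8 arrays. limma's lmFit and eBayes were fitted to the 8 arrays together with 1 coefficient per mutant, 4 residual degrees of freedom and 7.07 in total after moderation. A gene passed at a Benjamini-Hochberg adjusted p under 0.05, two-sided. Errors are SEs of that fit on the log2 scale, n = 2 arrays per mutant. They pool the spread of all 4 mutants, so they can be too small for a mutant whose arrays differ more. This may apply most to lntR, whose pair of arrays had the lowest correlation (r = 0.79). Differences between mutants are contrasts of the same fit. On simulated data with the real genes' spread, a change of 1 on the log2 scale was recovered for 98.5% of changed genes in lntR, 98.5% in nahR, 100% in nagR1 and 100% in nagR2, among 1841 genes. The false share among the simulated calls was 5.3%, 4%, 4.9% and 5% in that order. The simulated genes and arrays were independent, and each gene had the same spread in all mutants. On the real arrays, deviations of same-numbered arrays correlated between mutants at an r of up to 0.76. The recovered and false shares therefore do not show how the calls behave where mutants differ in spread or arrays deviate together. In the lntR simulation 4% of 100 unchanged 10-gene lists had a camera p below 0.05. Those lists were random independent genes, so this does not test camera on correlated genes such as neighbouring tags.

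Lists were tested with limma's camera (preset inter-gene correlation 0.01, Benjamini-Hochberg over lists and mutants), again with an estimated correlation, and with fry. Camera asks whether a list's genes shifted relative to the other genes. The files name genes by locus tag only. The reference table covers another strain of the species (assembly ASM102517v1), and 0 of the 1841 tags matched it. So 16 lists defined by words in gene products, fixed before the data were examined, stayed empty and were not used. The 5 lists used are windows of locus tags, fixed at the same time and labelled from background knowledge of the strain: the lnt window (Bbr_1550 to Bbr_1560), the nah window (Bbr_1582 to Bbr_1592), the first and second nag windows (Bbr_1245 to Bbr_1252 and Bbr_0844 to Bbr_0854) and the nan window (Bbr_0160 to Bbr_0172). The window names were not checked against an annotation of this strain and may be wrong, so they serve only as names of tag ranges. The files do not show which tag is which regulator, so an inactivated gene could not be looked up by name.

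The rule for named genes, also fixed before, takes each regulator's own gene where the files name it, per mutant the 15 largest rises and 10 largest falls past the threshold and alike on both arrays, up to 4 members of each window, up to 10 genes past the threshold alike in 3 or more mutants (or else in 2), and the 5 largest differences in each direction between mutants. Because the tags carry no names here, at most 2 risen and 2 fallen tags outside the windows are printed per comparison. Runs of at least 3 neighbouring tags changed 2-fold or more in 1 direction were chosen after the values were seen and compared with 1000 shuffles of gene order. Overlaps were set against the product of the list sizes over 1841 genes (Fisher's exact test, two-sided) and against 100 simulations of unchanged mutants that share the wild-type error. The simulations hold no changed genes, so they give a baseline for the covariance and none for shared calls.

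Alternatives were the scanner's processed signals, no background correction, a normexp offset of 10, median centring, a filter on dim probes, the median of a gene's probes, other sets of arrays in the fit, a replicate block, scaling between arrays, an intensity trend in the variance prior, the ratio threshold, the design text's Cyber-T test (written anew, with a window of 101 genes and a prior weight of 10, which are not given in the sources used here), the deposited value table, and leaving out each array. Additions made after the data were seen are named where they appear. Tests on features without a locus tag (transfer RNAs, the TetW marker) were fitted to all features shared by the 8 arrays, or for TetW by the 6 arrays that carry it.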

Results

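Transcript levels were measured on 2-colour arrays in 4 regulator mutants of *Bifidobacterium breve* UCC2003, each against the wild type, with ribose as carbon source. The series' title places the question in the use of human milk oligosaccharides, so the comparisons ask which genes change when each regulator is lost without such a sugar in the medium. Each mutant had 2 arrays of opposite dye orientation. After both were turned to mutant over wild type, the arrays of a pair correlated across the 1841 genes at r = 0.79 for lntR, 0.82 for nahR, 0.97 for nagR1 and 0.89 for nagR2 (genes are not independent replicates). The median signal of gene spots on an array ran from 468.3 to 2222.6 intensity units in the mutant channel and from 785.5 to 2206 in the wild-type channel, and at least 93.6% of spots were well above background in either. The number of arrays limits the precision. Among the arrays of this series the lntR pair and the nahR pair were each alone on a slide, and the nagR1 and nagR2 arrays shared another. Every ratio was taken within an array, but slide and mutant cannot be told apart for lntR and nahR. The lntR arrays also have a design with other probes, so design and mutant cannot be told apart where lntR is compared with another mutant. What nagR1 and nagR2 have in common cannot be told apart from their slide either.

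The TetW feature, a tetracycline resistance gene of the kind used to select insertion mutants, was held against the labels. It is on the 6 arrays of nahR, nagR1 and nagR2 and not on those of lntR. The 2 features of the plasmid pNZ44 on the same 6 arrays did not pass in any of these mutants, so they show no direction. TetW was higher in the mutant channel of nagR1 (log2 ratio 3.32 ± 0.41 SE, n = 2 arrays, adjusted p = 0.00082) and of nagR2 (4.55 ± 0.41, n = 2, adjusted p = 0.00074). On the arrays labelled nahR it was lower in the channel labelled mutant (n = 2, adjusted p = 0.000289). That channel lay near its negative controls, so the fitted log2 ratio of -6.17 depends on the background correction. Without background subtraction the labelled wild type was 20.4-fold brighter on replicate 1 and 71.8-fold on replicate 2. The wild-type channel of nagR2 replicate 2 was near its controls too (4 of 32 spots well above background), and the mutant channel was 16.2-fold brighter there. In the channel labelled mutant of nahR, 0 of 32 TetW spots were well above background on replicate 1 and 7 of 32 on replicate 2. In the channel labelled wild type all 32 were on both. TetW thus went against the labels on both arrays, and these are called the arrays labelled nahR below. Their directions are given as labelled and would turn if the channels were exchanged. No marker checks the direction of the lntR arrays.

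**Figure D1:**
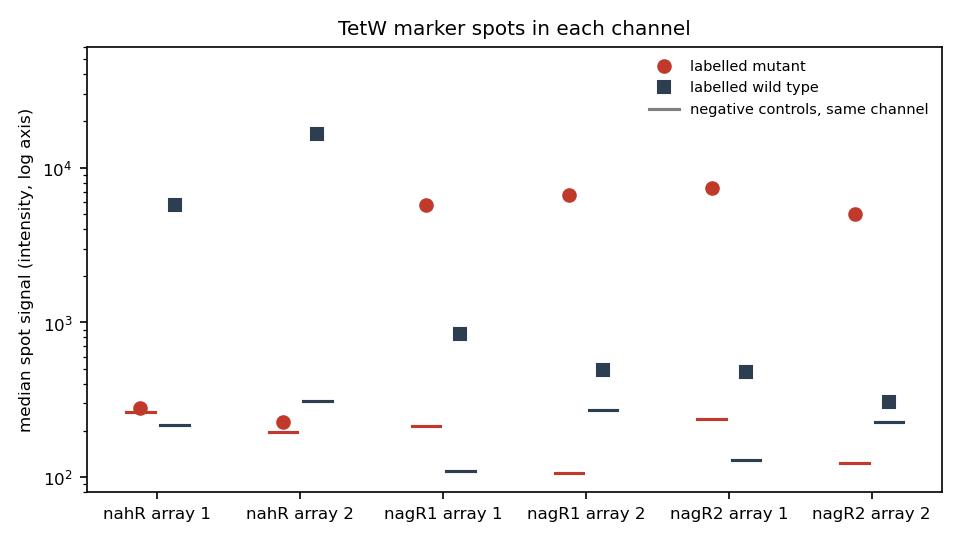
Median signal of the TetW spots (intensity, log axis) in the channel labelled mutant (circles) and the channel labelled wild type (squares) of each of the 6 arrays, with the median negative-control signal of the same channel as a line. On the arrays labelled nahR the labelled wild type reads 5702 and 16377 and the labelled mutant 280 and 228, whereas the mutant channel is the brighter on the 4 nagR1 and nagR2 arrays.

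In the nagR1 mutant the largest rises lay in neighbouring genes. In the first nag window, named for N-acetylglucosamine genes, Bbr_1248 was 11.5-fold higher than in the wild type (log2 3.52 ± 0.13, adjusted p = 8.22e-06). Bbr_1247 was 8.30-fold higher (log2 3.05 ± 0.09, adjusted p = 4.71e-06). Bbr_1250 rose by 1.77 on the log2 scale. Between them Bbr_1249 averaged 1.16, but this rested on 2 of its 5 probes, and with the median of its probes it lay at 0.35. Of the 8 genes of this window 4 rose, 2 fell and 2 did not pass, and 4 rose and 2 fell adjusted over the list alone. As a set it did not pass camera (median log2 0.59, adjusted p = 0.0699, and 0.371 with an estimated correlation), but passed without nagR1 replicate 1 (0.025) or replicate 2 (0.0475) and in 3 other settings. In the nah window, named for N-acetylhexosamine and lacto-N-biose genes, the 6 neighbours Bbr_1585 to Bbr_1590 rose together by 1.77 to 2.54. Bbr_1590 was 5.80-fold and Bbr_1586 5.16-fold higher. Another 2 of the window's 11 genes fell and 3 did not pass (6 rose and 3 fell adjusted over the list alone). Its median shift was 1.77 (camera adjusted p = 0.0434). The call ended with an estimated correlation (adjusted p = 0.371) and in 8 other settings. Among them were a replicate block (0.053), median centring (0.151), either lntR array left out (0.107 each), and nahR replicate 1 (0.0507) or replicate 2 (0.0549) left out.

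Smaller rises in nagR1 covered the other windows. The 16S rRNA feature was 2.76-fold lower in nagR1 (adjusted p = 0.00334), and a difference in RNA composition or quality was not tested. The nan window is named for sialic acid genes. Of its 12 genes 11 rose and 1 did not pass, and all 12 rose adjusted over the list alone. Its median was 0.60, with Bbr_0169 at 1.28 ± 0.12 and Bbr_0168 at 0.98 ± 0.15 (camera adjusted p = 0.000148, but adjusted p = 0.313 with an estimated correlation). The lnt window is named for lacto-N-tetraose genes. In it 7 of 10 genes rose and 3 did not pass, over all genes and adjusted over the list alone (median 0.48). Bbr_1550 rose by 0.72 ± 0.07 there (camera adjusted p = 0.00758, and adjusted p = 0.313 with an estimated correlation). In the second nag window 8 of 11 genes rose, 1 fell and 2 did not pass by either adjustment (median 0.34). Its camera adjusted p was 0.0295, and 0.371 with an estimated correlation. Outside the windows, Bbr_1883 was 4.38-fold higher and Bbr_0118 3.88-fold lower (log2 -1.96 ± 0.07). A run of 3 neighbours, Bbr_1408 to Bbr_1410, fell by a mean log2 of -1.29, though with the median of each gene's probes they did not all fall 2-fold. In all, 503 of 1841 genes were higher and 535 lower in nagR1 (limma, adjusted p under 0.05), 11 and 2 of them by more than 3-fold. Most changes were small, with a median size of 0.39 on the log2 scale, and the count was 569 without replicate 1 and 507 without replicate 2 of nagR1.

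**Figure D2:**
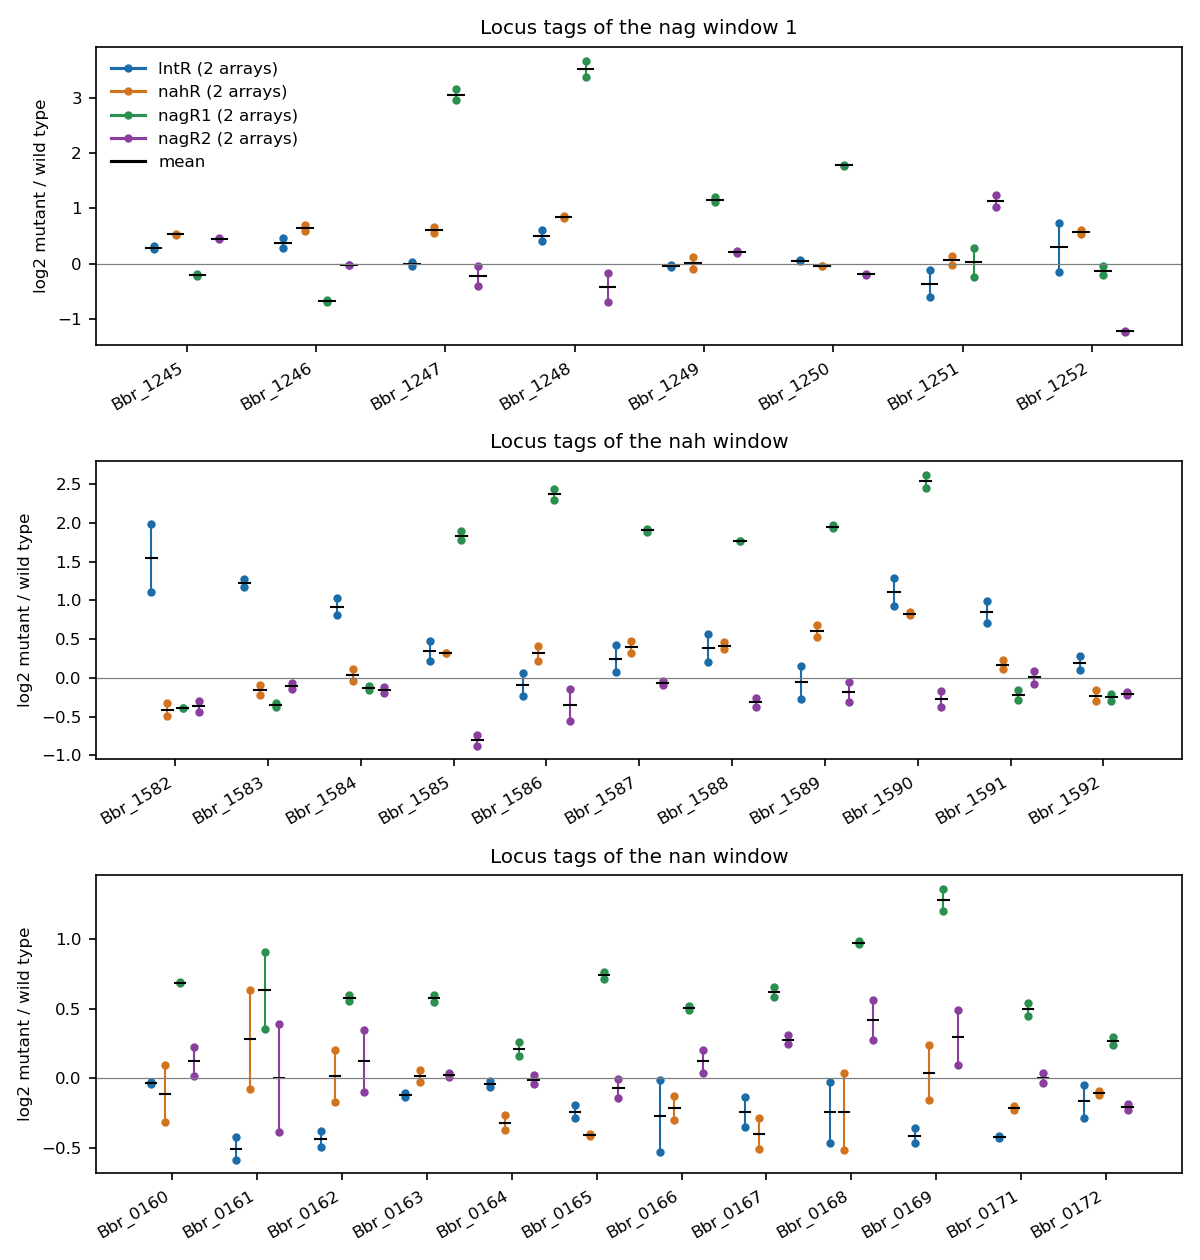
log2 ratio of mutant over wild type (as labelled) for each gene of the first nag, nah and nan windows, by locus tag. Points are the 2 arrays of a mutant joined by a line, and the black bar is their mean. In nagR1 Bbr_1247 and Bbr_1248 lie at 3.05 and 3.52 and the genes Bbr_1585 to Bbr_1590 between 1.77 and 2.54, with the arrays of a pair close together.

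In the nagR2 mutant no gene that passed changed more than 3-fold. Bbr_1597 was 2.67-fold (log2 1.42 ± 0.08, adjusted p = 0.000156) and Bbr_1598 2.35-fold higher. Bbr_1447 was 2.56-fold lower (log2 -1.35 ± 0.09), and the 4 neighbours Bbr_1416 to Bbr_1419 fell by a mean of -1.08 (a run of 3 with the median of their probes). In the first nag window Bbr_1252 fell (-1.22 ± 0.18, adjusted p = 0.00401, but 0.0775 without nagR2 replicate 1 and 0.0589 without replicate 2). Bbr_1251 had a mean of 1.13 ± 0.15, but this rested on 2 of its 6 probes, at a mean of 4.08, while the others averaged -0.34. With the median of its probes it lay at -0.22, and without nagR2 replicate 2 it did not pass (adjusted p = 0.0569). By either adjustment 3 of the 8 genes rose, 3 fell and 2 did not pass. The set's median was -0.11 (-0.03 without nagR2 replicate 1) and its camera direction upward (adjusted p = 0.89, and 0.931 with an estimated correlation).

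In the nah window of nagR2 2 of 11 genes fell and 9 did not pass, by either adjustment. Its median was -0.20, with Bbr_1585 at -0.81 ± 0.07 (camera adjusted p = 0.025, and adjusted p = 0.314 with an estimated correlation). The median was -0.31 without nagR2 replicate 2. In the second nag window 3 of 11 rose and 1 fell (4 and 1 adjusted over the list alone), with a median of 0.19. Its camera adjusted p was 0.0295, 0.371 with an estimated correlation and 0.163 without nagR2 replicate 1, where the median was 0.06 (0.30 without replicate 2). In the lnt window 1 of 10 rose by either adjustment, Bbr_1560 at 0.35 ± 0.08. It did not pass in 7 settings, among them without nagR2 replicate 1 (adjusted p = 0.219) or 2 (0.169), without either nagR1 array (0.0528 each) and with median centring (0.0692). The window's median was 0.14 (camera adjusted p = 0.0485, and adjusted p = 0.313 with an estimated correlation). That call also ended in 9 other settings, among them without nagR2 replicate 1 (adjusted p = 0.115, median 0.09) and without lntR replicate 2 (0.0516). In the nan window 1 of 12 rose, and 0 adjusted over the list alone (median 0.07, or 0.02 and 0.22 without nagR2 replicate 1 and 2, camera adjusted p = 0.272, and 0.613 with an estimated correlation). Over all genes 204 were higher and 264 lower. With scaling between arrays the total was 984, beside 970 for nagR1, so the order of the mutants by count depends on the scaling. Without nagR2 replicate 1 the count was 66 and without replicate 2 it was 95. It was 296 without either nagR1 array and 922 without either lntR array, since the arrays share 1 estimate of the spread.

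In the lntR mutant, as labelled, the strongest change was a fall of 4 neighbouring genes. Bbr_0530 was 6.01-fold lower (log2 -2.59 ± 0.06, adjusted p = 9.56e-07), and Bbr_0527 to Bbr_0530 fell by a mean of -2.03. Among rises, Bbr_1293 was 4.04-fold (2.02 ± 0.05, adjusted p = 1.81e-06) and Bbr_1464 3.80-fold higher, and the 4 neighbours Bbr_0973 to Bbr_0976 rose by a mean of 1.24 (a run of 3 with the median of their probes). In the nah window 9 of 11 genes rose and 2 did not pass, by either adjustment. Bbr_1582 stood at 1.54 ± 0.18 and Bbr_1583 at 1.23 ± 0.06, and the median was 0.38, or 0.22 without lntR replicate 1 (camera adjusted p = 0.00758, and adjusted p = 0.313 with an estimated correlation). In the lnt window 6 of 10 genes fell and 4 did not pass, by either adjustment, with a median of -0.35. Its most changed gene, Bbr_1560, ranked only 58 of 1841 by size of change. Bbr_1560 fell by 0.90 ± 0.08 (arrays -0.71 and -1.08) and Bbr_1559 by 0.79 ± 0.10 (arrays -0.55 and -1.02). The pooled errors are small beside these differences between arrays. Under median centring the 2 genes lay at -0.37 and -0.19 and did not pass. The camera adjusted p of the window was 0.0295, 0.313 with an estimated correlation and 0.111 with median centring, and 0.0872 without lntR replicate 2.

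In the nan window of lntR 5 of 12 genes fell and 7 did not pass, by either adjustment. The median was -0.25 (-0.39 without lntR replicate 1), with Bbr_0171 at -0.42 ± 0.05, which did not pass in the lntR arrays by themselves (camera adjusted p = 0.0295, 0.371 with an estimated correlation and 0.107 without lntR replicate 2). In the first nag window 3 of 8 rose by either adjustment (median 0.17, but 0.01 without lntR replicate 1, camera adjusted p = 0.287, and 0.601 with an estimated correlation). In the second 4 of 11 rose and 1 fell (2 and 1 adjusted over the list alone, median 0.12, or 0.20 without lntR replicate 2, camera adjusted p = 0.446, and 0.74 with an estimated correlation). In all 587 genes were higher and 584 lower, 3 and 6 of them by more than 3-fold. The 2 lntR arrays by themselves gave 331 genes, beside 1171 in the joint fit, whose errors pool the spread of all 4 mutants.

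On the arrays labelled nahR 1 gene stood apart. Bbr_1554, in the lnt window, was 18.3-fold lower in the channel labelled mutant (log2 -4.19 ± 0.29, adjusted p = 0.000226), with -4.92 and -3.46 on the 2 arrays and all 6 of its probes between -4.40 and -4.00. Bbr_0766 was 3.95-fold (1.98 ± 0.08, adjusted p = 4.29e-05) and Bbr_0765 3.83-fold higher. Bbr_0119 was 1.99-fold lower. With the channels exchanged each of these would turn. In the lnt window 6 of 10 genes fell and 4 did not pass, by either adjustment (median -0.44, camera adjusted p = 0.00113, and adjusted p = 0.313 with an estimated correlation). One of these falls, Bbr_1555 at -0.39, rested on 1 of its 5 probes, and with the median of its probes it lay at 0.05 and did not pass. With median centring Bbr_1558, Bbr_1559 and Bbr_1560 fell by less, to -0.36, -0.44 and -0.43, and did not pass. Bbr_1559 did not pass without nahR replicate 2 either (adjusted p = 0.056). In the nah window 5 of 11 rose and 1 fell (6 and 2 adjusted over the list alone). Bbr_1590 stood at 0.83 ± 0.10 and the median at 0.32 (camera adjusted p = 0.0731, 0.0279 with median centring and 0.371 with an estimated correlation).

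In the first nag window of the arrays labelled nahR 5 of 8 genes rose and 3 did not pass, by either adjustment, with Bbr_1248 at 0.84 ± 0.13 (not past without nahR replicate 2, adjusted p = 0.0641) and a median of 0.55 (camera adjusted p = 0.0143, and adjusted p = 0.314 with an estimated correlation). In the second 2 of 11 rose by either adjustment. Its median was -0.03 (-0.16 and 0.13 without nahR replicate 1 and 2), its mean 0.05 and its camera direction upward (adjusted p = 0.513, and 0.757 with an estimated correlation). In the nan window 4 of 12 fell by either adjustment (median -0.16, or -0.27 without nahR replicate 1, camera adjusted p = 0.0485, and adjusted p = 0.383 with an estimated correlation). That call also ended in 11 other settings. Among them were nahR replicate 2 left out (adjusted p = 0.416, median -0.04), lntR replicate 1 (0.0693) or 2 (0.0831), and nagR2 replicate 1 (0.0588) or 2 (0.0504). Over all genes 297 were higher and 275 lower, 2 and 1 of them by more than 3-fold. The count was 243 without nahR replicate 1, 125 without replicate 2 and 950 without either lntR array.

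The 2 nag regulators were compared within the slide they share. Bbr_1248 differed by 3.94 ± 0.18 on the log2 scale, nagR1 minus nagR2 (adjusted p = 2.8e-05), and Bbr_0118 by -2.75 ± 0.09. The nah window differed by a median of 1.97 (6 of 11 genes higher in nagR1, and 6 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.00255). The nan window differed by 0.53 (7 of 12 higher, and 10 adjusted over the list alone, camera adjusted p = 0.000175). The lnt window differed by 0.27 (3 of 10 higher, adjusted p = 0.0496). With an estimated correlation each of these 3 had an adjusted p = 0.255. The nag windows did not pass. The first differed by a median of 1.02 (5 of 8 genes higher and 3 lower in nagR1, by either adjustment, camera adjusted p = 0.116). The second differed by 0.02 (camera adjusted p = 0.671). In all 582 genes differed, 284 higher and 298 lower in nagR1, and 1128 with the 4 arrays of the shared slide alone. The count fell to 364 with the scanner's processed signals, and to 111, 157, 192 and 180 without nagR1 replicate 1, nagR1 replicate 2, nagR2 replicate 1 and nagR2 replicate 2. It was 1017 without either lntR array.

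Against lntR, nagR1 was higher by 3.05 ± 0.13 for Bbr_1247 and lower for Bbr_1293 (-2.74 ± 0.08), and all 12 nan genes were higher (median 0.89, camera adjusted p = 0.000468). The lnt window was higher by 0.77 (8 of 10 genes, adjusted p = 0.00811). With an estimated correlation both had an adjusted p = 0.255. The window counts in this paragraph are the same adjusted over the list alone. The contrasts with lntR join 2 array designs, so probe design and mutant cannot be told apart in them. For nagR1 minus lntR 1290 genes differed, and 746 with the sign of the lntR arrays turned. That turn, like the other turned signs, was chosen after the data were seen. With that turn the lnt window differed by 0.10 and did not pass (camera adjusted p = 0.633). The nah window, which as labelled did not pass (1.38, adjusted p = 0.566), passed at 1.89 (adjusted p = 4.61e-07), as did both nag windows (adjusted p = 0.00936 and 0.03). With an estimated correlation the adjusted p of these 3 was 0.153, 0.288 and 0.354. The largest differences were then Bbr_1248 (4.03) and Bbr_0530 (-2.89). Against the arrays labelled nahR, nagR1 was higher by 4.23 ± 0.41 for Bbr_1554 and lower for Bbr_1408 (-2.56 ± 0.15). The lnt window was higher by 0.83 (9 of 10 genes), the nah window by 1.34 (6 of 11 higher and 1 lower) and the nan window by 0.72 (11 of 12), with camera adjusted p = 0.000175, 0.0485 and 0.000175. With an estimated correlation the adjusted p was 0.255, 0.399 and 0.255. A total of 982 genes differed, and 721 with the sign of the arrays labelled nahR turned. Turned, the largest differences were Bbr_1248 (4.36) and Bbr_1554 (-4.16). The lnt window then differed by -0.07 and did not pass (camera adjusted p = 0.843), with the nah window at 2.16 and the nan window at 0.45, and both nag windows passed (adjusted p = 0.000683 and 0.0331, but 0.222 and 0.379 with an estimated correlation). Without nagR1 replicate 2 the count was 638. Between lntR and the arrays labelled nahR 813 genes differed, with Bbr_1554 (4.71 ± 0.41) and Bbr_0530 (-3.15 ± 0.08) at the ends as labelled. With the nahR sign turned the ends were Bbr_1293 (2.87) and Bbr_1554 (-3.67). The count was 1096 with either sign turned, 498 without nahR replicate 1 and 518 without replicate 2. As labelled no window passed camera in that contrast (lowest adjusted p = 0.139). With the nahR sign turned 4 passed, among them lnt at -0.78 (adjusted p = 0.00161) and nah at 0.80 (adjusted p = 0.00147), and with an estimated correlation the lowest adjusted p was 0.222.

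Across mutants, 143 genes passed the threshold in the same direction in 3 or more (78 higher, 65 lower), 17 of them in all 4, and 0 with a 2-fold change in each. With the nahR sign turned 109 did (46 higher, 63 lower), 4 of them in all 4, and with the lntR sign turned 202 (61 higher, 141 lower), 21 of them in all 4. The count that independent lists would give in 3 or more mutants was not computed, so these counts do not show a common response. As labelled Bbr_1720 was higher in all 4, at 1.07 in lntR, 0.47 on the arrays labelled nahR (-0.47 turned), 0.70 in nagR1 and 0.75 in nagR2. nagR1 and nagR2 shared 172 lower genes against 76.7 for independent lists (Fisher's exact test, adjusted p = 2.43e-39) and 80 higher ones against 55.7 (adjusted p = 0.000147). Fisher's test takes genes as independent, which neighbouring genes are not, and both lists rest on the same estimate of each gene's spread. These p-values are therefore no test of agreement between cultures. Their fold changes correlated across genes at r = 0.36, with a covariance of 0.0403. Unchanged mutants with a common wild type, simulated from the spread between arrays, gave an r of 0.50, a covariance of 0.00497 and a mean of 0 shared calls. Without changed genes few or none are called, so that 0 is no baseline for the shared counts. A deviation of a wild-type culture common to both arrays of a mutant is not in the spread between arrays, so part of the excess may still come from shared controls. nagR1 and nagR2 were also the only pair of mutants on a common slide, so a slide effect cannot be told apart from a shared response.

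The fold changes of lntR and nagR1 opposed each other. They shared 52 higher and 52 lower genes, where independent lists give 160.4 and 169.7, and 599 went opposite ways against 330.1. Their r across genes was -0.38 (0.38 with a sign turned) and the covariance -0.0681. Between arrays of the same dye orientation r was -0.30 and -0.44. The labels state the dyes, so the direction was kept. lntR and the arrays labelled nahR shared 158 higher genes against 94.7 and 115 lower against 87.2, and 119 went opposite ways against 181.9, with r = 0.21. With the nahR sign turned r was -0.21 and the 119 genes would be the shared ones, fewer than the 181.9 of independent lists. Their covariance was 0.0256, and the simulation with a common wild type gave an r of 0.50, a covariance of 0.00506 and a mean of 0 shared calls. That 0 is no baseline for the shared counts either, since the simulation held no changed genes. nagR1 and the arrays labelled nahR had r = -0.12, or 0.12 turned. By array r was 0.01 and -0.01 for nahR replicate 1, and -0.24 and -0.21 for replicate 2. They shared 58 higher genes against 81.1 and 77 lower against 79.9, and 237 went opposite ways against 161.4. Those 237 would be the shared ones if the nahR channels were exchanged. The count of genes shared by 3 or more was between 36 and 72 without an array of nahR, nagR1 or nagR2, and 303 and 388 without lntR replicate 1 and 2.

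**Figure D3:**
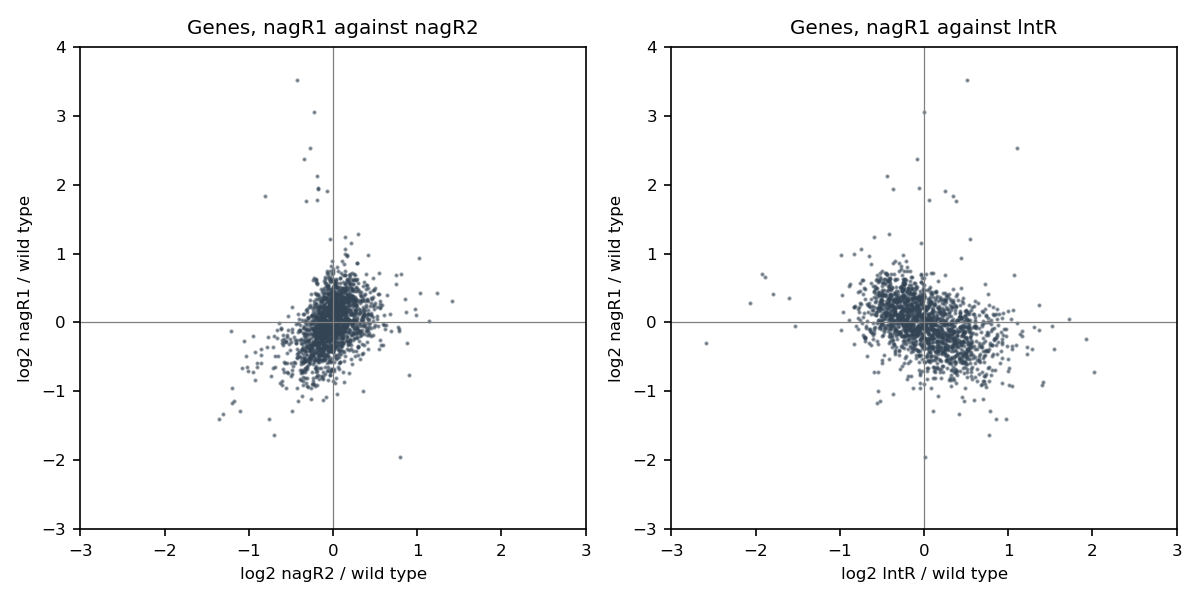
log2 ratio of each gene in nagR1 (vertical) against nagR2 (left) and lntR (right), 1 point for each of 1841 genes, as fitted over 2 arrays per mutant. The cloud rises with r = 0.36 on the left and falls with r = -0.38 on the right.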

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

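The tests of explanations in this part were all chosen after the pattern was seen. Results stand out here because effects of mutants differed in a test of the difference itself, or because a signal lay outside the gene measurements. The numbers of genes that differed were 582 for nagR1 minus nagR2, 982 for nagR1 minus the arrays labelled nahR, 1290 for nagR1 minus lntR and 813 for lntR minus the arrays labelled nahR. As labelled, the largest single differences in each direction were, in that order, Bbr_1248 (3.94) and Bbr_0118 (-2.75), Bbr_1554 (4.23) and Bbr_1408 (-2.56), Bbr_1247 (3.05) and Bbr_1293 (-2.74), and Bbr_1554 (4.71) and Bbr_0530 (-3.15), on the log2 scale. Median differences of windows past camera's preset test were 0.27 (lnt), 1.97 (nah) and 0.53 (nan) for nagR1 minus nagR2. They were 0.83 (lnt), 1.34 (nah) and 0.72 (nan) for nagR1 minus the arrays labelled nahR, and 0.77 (lnt) and 0.89 (nan) for nagR1 minus lntR. With the nahR sign turned the values for nagR1 minus nahR became -0.07 (lnt), 2.16 (nah) and 0.45 (nan), and the ends became Bbr_1248 (4.36) and Bbr_1554 (-4.16). Those of lntR minus nahR became Bbr_1293 (2.87) and Bbr_1554 (-3.67). With the lntR sign turned the lnt difference of nagR1 minus lntR became 0.10, the nan difference 0.30 and the nah difference 1.89, which then passed, with Bbr_1248 (4.03) and Bbr_0530 (-2.89) at the ends. None of these windows passed with an estimated correlation.

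The TetW marker was outside the gene comparisons. Its fitted log2 ratio was 3.32 in nagR1 and 4.55 in nagR2, but -6.17 on the arrays labelled nahR. The ratio of nahR, and that of nagR2 replicate 2, has a channel near its negative controls, so its size depends on the background correction. Without background subtraction the brighter channel led by 20.4-fold and 71.8-fold on the nahR arrays and by 16.2-fold on that nagR2 array. Binding of wild-type RNA by the TetW probes is argued against, since on the nagR1 and nagR2 arrays the labelled wild type held at most 13.4% of the mutant channel's TetW signal above the negative controls. A record of the dyes the wrong way round on both nahR arrays is a candidate explanation that stays open, because the value of -6.17 is what raised it and is no test of it. Whether the labels lntR and nahR are also exchanged could not be tested, because the files do not name the regulators' genes. On the arrays labelled nahR the most changed gene of all was Bbr_1554 of the lnt window. On the lntR arrays the most changed gene of the nah window ranked 10 by size, and the most changed gene of all, Bbr_0530, lay in neither window. The window names are unchecked, so these ranks give no ground for an exchange. A wild-type culture with a tetW plasmid was not tested.

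The opposition of lntR and nagR1 was the other pattern of note. Error from a common wild-type RNA is argued against as labelled, since it would give a positive covariance (0.00508 in simulation) and -0.0681 was found. The covariance would be positive were the lntR sign turned, so this argument holds only with the dyes as labelled. A dye effect common to both array designs is argued against as labelled. It would make r positive between arrays of the same dye orientation, and -0.30 and -0.44 were found. The pairs of opposite orientation (-0.28 and -0.46) do not bear on this, since a dye effect would make them negative too. The choice of scaling did not end it, with r between -0.35 and -0.55 over the other ways of processing. A dye record the wrong way round on the lntR arrays could not be decided: no marker is on their design, and with the sign turned lntR correlated at -0.09 with nagR2 though at 0.38 with nagR1. The nagR2 value differed by array: as labelled, lntR replicate 1 had an r of 0.19 and 0.17 with the nagR2 arrays, and replicate 2 -0.07 and -0.01. An opposite effect of losing these regulators remains open and was not tested.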

How the results depend on the processing

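The settings with a turned sign, without both arrays labelled nahR, with the shared slide alone and with a 2-fold size were chosen after the data were seen. The causes of the changes below were not tested, except that other sets of arrays change the pooled spread and thresholds on ratio remove small changes by construction. With a ratio over 3 or under 1/3 added, the counts became 9 for lntR, 3 for nahR, 13 for nagR1 and 0 for nagR2, and 13, 18, 46 and 10 for nagR1 minus nagR2, nagR1 minus nahR, nagR1 minus lntR and lntR minus nahR. The Cyber-T form at the study's thresholds gave 9, 3, 13 and 0 for the 4 mutants, and after Benjamini-Hochberg 951 for nagR2. For that 0, 764 genes of nagR2 had an unadjusted limma p under 0.05. Each array design by itself gave 331 (lntR), 950 (nahR), 922 (nagR2) and 1017 (nagR1 minus nagR2). Each mutant's arrays by themselves gave 331 for lntR and 800 for nagR2. Scaling between arrays gave 923 (lntR), 925 (nahR), 970 (nagR1), 984 (nagR2) and 255 genes shared by 3 or more mutants. The shared slide alone gave 1032 for nagR2 and 1128 for nagR1 minus nagR2. That difference was 364 with processed signals and 362 with the deposited value table. Turning the lntR sign gave 746 for nagR1 minus lntR and 202 shared genes, and turning the nahR sign 109. Of 143 shared genes 0 changed 2-fold in 3 mutants. Of the 13 window calls 0 held with an estimated correlation (lowest adjusted p = 0.313). Without both arrays labelled nahR the counts were 1133 (lntR), 1006 (nagR1) and 384 (nagR2).

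Leaving out 1 array at a time, with a lone array assumed to vary like the other groups, gave 1054 to 1246 genes for lntR, 125 to 950 for nahR, 507 to 1329 for nagR1 and 66 to 922 for nagR2. The differences ranged from 111 to 1017, 638 to 1290, 1027 to 1433 and 498 to 1152 in the order above. Window calls ranged from 8 (without lntR replicate 2) to 14, and shared genes from 36 to 388. Bbr_1251 in nagR2 reversed to -0.22 with the median of its probes, the cause lying in 2 of 6 probes. For the named genes the other settings kept direction and side of the threshold in 2087 of 2181 cases, and leaving out an array in 1221 of 1320.

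The replicate block, which is also the dye orientation, gave 1245, 666, 1121 and 592 genes for lntR, nahR, nagR1 and nagR2. It ended the nah window's call in nagR1 (adjusted p = 0.053) and no other window call. Same-numbered arrays deviated together in 5 of 6 pairs of mutants (r of deviations across genes from 0.25 to 0.76) and not for lntR and nagR1 (-0.12). Every pair of mutants on the same array design had it (0.25, 0.52 and 0.76), and the exception joins 2 designs with other probes. The shared deviation coincides with the dye orientation, and a dye effect was not told apart from other causes. The main fit did not take the numbers as pairs. It thus treats the arrays of different mutants as independent, which they were not. A slide term as a random block was not run, since the slides are sums of the mutants' own terms. The ratio threshold and the Cyber-T form do not apply to camera. Signal limited few genes: 2 of 1841 (in lntR) had no spot well above background in the mutant channel.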

Other observations

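The features without a locus tag include 20 transfer RNA features, 1 of them of unknown kind, on both designs, which no comparison above used. In lntR 4 were higher and 9 lower (limma, fitted to all shared features), in nagR1 2 and 5, in nagR2 0 and 5, and on the arrays labelled nahR 0 and 3. The aspartate tRNA fell in lntR (log2 -0.98 ± 0.08 SE, n = 2 arrays, adjusted p = 0.000139) and on the arrays labelled nahR (-0.38 ± 0.08), and rose in nagR1 (0.93 ± 0.08, adjusted p = 0.000163). The asparagine tRNA fell in lntR (-0.77 ± 0.08) and on the arrays labelled nahR (-0.62 ± 0.08) and rose in nagR1 (0.49 ± 0.08). The glutamine tRNA fell in nagR1 (-0.90 ± 0.11), in nagR2 (-0.80 ± 0.11) and by less in lntR (-0.44 ± 0.11, arrays -0.67 and -0.21). The glutamate tRNA fell in nagR2 (-0.79 ± 0.13) and lntR (-0.58 ± 0.13, arrays -0.90 and -0.27). The 16S rRNA feature, also without a tag, was 2.76-fold lower in nagR1 (log2 -1.47 ± 0.27, adjusted p = 0.00334, arrays -0.94 and -1.99) and did not pass in the other mutants. Whether the nagR1 RNA differed in composition or quality was not tested. The 23 plasmid, insertion-element and spike features had an SD of 0.06 to 0.16 on the log2 scale over features, and at most 2 passed in a mutant. The differences between mutants were not tested for these features.

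Runs of neighbouring genes that changed 2-fold or more were far more frequent than in shuffled gene order. There were 2 in lntR, 3 in nagR1 and 1 in nagR2, against at most 1 in any of 1000 shuffles, and 0 on the arrays labelled nahR, where 5 genes changed that much. With the median of each gene's probes, chosen after the data were seen, 1 run remained in nagR1, Bbr_1585 to Bbr_1590, since the run from Bbr_1247 to Bbr_1250 needs the 2 high probes of Bbr_1249. The counts in lntR and nagR2 were then 2 and 1, with Bbr_0973 and Bbr_1419 no longer in their runs.

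The tests in this paragraph were chosen after the result was seen. In each mutant with TetW on its design, a window gene had a few probes far from the rest of the gene. In nagR2 it was Bbr_1251, with the widest spread of all genes (2 of 6 probes at 4.07 and 4.10). In nagR1 it was Bbr_1249, second in rank (2 of 5 probes at 2.42 and 2.50, the rest averaging 0.29), and on the arrays labelled nahR it was Bbr_1555, first in rank (1 of 5 probes at -2.54, next to Bbr_1554). Binding of RNA from the marker, or from plasmid sequence common to nagR1 and nagR2, is argued against. In the other of these mutants TetW was high too. There the high probes of Bbr_1249 and Bbr_1251 had a mean over both arrays of at most 0.13. They reached at most 0.54 on a single array, and the Bbr_1251 probes read -1.04 and -1.37 on nagR1 replicate 1. RNA from plasmid sequence particular to 1 mutant was not tested. Transcription out of an inserted plasmid into part of 1 gene may account for the steps, but this stays open. The genes were picked for their spread, so their ranks of 2 or better are no support, and the insertion sites are not in the files used here. As labelled the Bbr_1555 probe fell, which is against added transcription in the mutant unless the channels are exchanged.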
